A study of Glycine max with 4 samples.

How the data were processed

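ChIP-seq of GLYMA.08G357600 was carried out on early maturation embryos of soybean cultivar Williams 82, with 2 ChIP and 2 input samples. Per the labels' protocols, tissue was crosslinked for 10 minutes in 1% formaldehyde, chromatin was sheared by sonication to 100 to 500 bp, 1 ug of anti-peptide antibody was used, and libraries were amplified with 15 PCR cycles. Bowtie 0.12.7 and MACS2 are named in the submitters' processing notes. The MACS2 version, genome build, read filters and peak threshold are not given in the sources used here. The authors deposited 1 narrowPeak list per ChIP replicate, so peaks were called per replicate and not on pooled reads. The input samples were not analysed on their own here.

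Each deposited line gives a peak's position, its summit and 4 values. The deposited fold enrichment is a ratio of ChIP to local background at the summit. The deposited significance values are the −log10 of the p-value and the −log10 of the q-value at the summit, and the lowest −log10 q was 2.03 in replicate 1 and 2.05 in replicate 2. The deposited score was found to be 10 times the −log10 q cut to a whole number in all peaks but 1. Positions are printed counting from 1.

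Shared sites were one-to-one pairs of peaks overlapping by at least 50% of both. Overlap was tested against 100 seeded random placements of replicate 2's peaks, anywhere on the same chromosome or within the same 100 kb. The last peak end stood in for the length of each chromosome. Shares have exact Clopper-Pearson 95% intervals over peaks. These cover counting error only: they take peaks as independent and leave out variation between libraries. Poisson intervals of pileups also cover counting error only, since PCR copies are not independent molecules. Intervals of correlations and medians come from 500 bootstrap draws over peaks. The correlation, the overlap rules, the fold and q thresholds, the IDR alternative and the rule for named peaks were fixed before the data were examined. By that rule the 10 shared sites with the highest mean fold over both replicates are named by position when no annotation of the build is at hand. The analyses of chromosome position, spacing and pileup were added after the lists were seen.

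The ChIP pileup and the background at each summit were recovered by solving the deposited fold, (pileup + 1)/(background + 1), together with the deposited −log10 p, taken as a Poisson upper tail. Whole pileups, within 0.02 after division by one scale per list, came out for 100% of the peaks in each list. The scale was 1 in replicate 1 and 0.846 in replicate 2 for the ChIP library, and 0.978 and 1 for the background. The lowest background, taken as the genome-wide one, was 7.87 in replicate 1 and 6.09 in replicate 2. Steps between backgrounds gave a fragment length of 234 bp in replicate 1 and 217 bp in replicate 2, the width of the narrowest peak in each list. Reads per bp were the pileup at the genome-wide background divided by that length and scale, so depth is known only relative to the caller's genome size.

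Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The numbers of overlapping pairs were checked against bedtools 2.31.1 and were equal. On simulated data the pileup recovery returned 100% of 1984 and 1939 peaks, and the IDR fit called 86.75% of the 6000 simulated pairs that were reproducible, with 0.914% of its calls false. The simulated pairs had not been selected by a peak threshold, so these IDR rates need not hold for the deposited lists. Alternatives covered the peak threshold, the overlap rule, the strength measure, scaffolds and each replicate on its own. Planned analyses of position relative to genes, of bound genes and gene lists, and of sequence motifs were not run, because no genome or annotation of the lists' build was used here. The reference gene table used, of assembly Glycine_max_v4.0, has 0 rows with the target's locus ID, and none of its coordinates were used.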

Results

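Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the DNA occupied by the protein of the soybean locus GLYMA.08G357600 during early seed maturation, the stage at which embryos begin to fill with storage protein and oil. Embryos of the cultivar Williams 82, the line whose genome serves as the soybean reference, came from seeds of 6 to 7 mm. The 4 samples fell into 2 groups of 2 biological replicates. In the ChIP group, chromatin was precipitated with an antibody raised against amino acids 487 to 502 of the protein. In the input group, chromatin was sequenced without precipitation. Peak lists of ChIP replicates 1 and 2 were compared, and the input samples were not analysed on their own here. Library totals are not given in the sources used here. The ChIP depth recovered from the peak values was 0.0336 reads per bp of the peak caller's genome size in replicate 1 and 0.0332 in replicate 2.

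The first question was how many peaks each replicate had and how strongly they were enriched. Whether each peak marks binding of the protein was not tested. Replicate 1 had 15861 peaks, of which 15774 lay on the 20 chromosomes and 87 on 24 unplaced scaffolds. Replicate 2 had 10950 peaks, with 10894 on chromosomes and 56 on 15 scaffolds, so that replicate 1 had 1.45 times as many. Peaks were narrow, with a median width of 397 bp in replicate 1 and 364 bp in replicate 2, and together they covered 7.13 Mb and 4.44 Mb. Fold enrichment, the authors' value of ChIP over local background at each peak's summit, had a median of 4.62 in replicate 1 and ranged from 1.88 to 44.4. In replicate 2 the median was 5.09 and the range 2.00 to 39.4. Peaks with at least 10-fold enrichment numbered 2420 in replicate 1, or 15.3%, and 1774 in replicate 2, or 16.2%. Weak peaks made up more of the longer list: 5946 peaks of replicate 1, or 37.5%, were enriched less than 4-fold, against 2845 peaks, or 25.98%, in replicate 2. With only peaks of at least 4-fold kept, replicate 1 had 9915 and replicate 2 had 8105. The lists hold peaks of the ChIP group, and input could enter them only through the background of the authors' peak calling. No separate test against the input group was made here.

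The second question was which sites had a peak in both replicates. A pair of peaks covering at least 50% of each other was found at 9858 sites, which were 62.2% of replicate 1's peaks and 90.03% of replicate 2's (exact binomial 95% intervals 61.4 to 62.9% and 89.5 to 90.6%, counting error only). On the chromosomes 9806 sites were shared, whereas placing replicate 2's peaks at random on the same chromosomes gave 51.3 ± 7.37 (SD over 100 placements) and at most 72. Moving each peak only within its own 100 kb gave 144 ± 11.5 and at most 183. For both kinds of placement the one-sided permutation p was 0.0099, the smallest that 100 placements can give. Such placement takes no account of where reads can be placed. It therefore cannot separate binding of this protein from other features that both libraries share.

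Every strong peak had a counterpart in the other replicate. Among the strongest 20% of replicate 1's peaks and the strongest 30% of replicate 2's, 100% overlapped a peak of the other list by at least 1 bp. The share fell to 23.2% (21.1 to 25.3%) in the weakest 10% of replicate 1's peaks and to 84.8% (82.6 to 86.9%) in the weakest 10% of replicate 2's. The 5545 peaks found in replicate 1 alone had a median of 3.49-fold and none exceeded 8.12-fold. The 561 peaks found in replicate 2 alone had a median of 3.68-fold and none exceeded 5.86-fold. A stricter rule, an irreproducible discovery rate (IDR) of at most 0.01 computed from the ranks of fold enrichment, kept 4120 of the 10301 pairs that overlapped by at least 1 bp.

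**Figure D1:**
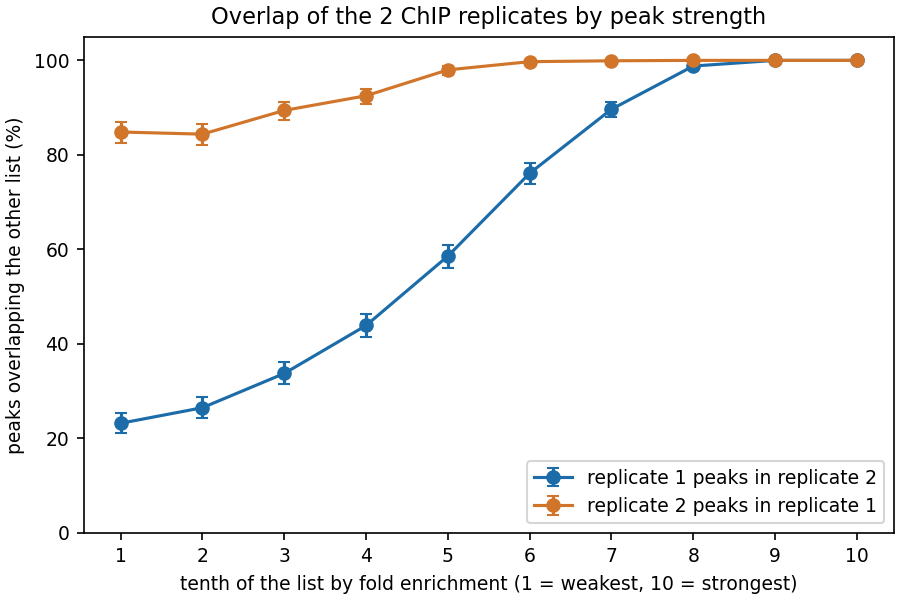
Share of peaks that overlap a peak of the other replicate by at least 1 bp (vertical axis, %) in 10 equal parts of each list from the weakest (1) to the strongest (10) by fold enrichment; bars are exact binomial 95% intervals. Replicate 1 rises from 23.2% to 100% and replicate 2 from 84.8% to 100%.

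At shared sites, peak strength and summit position were compared between replicates. Fold enrichment ranked the 9858 sites alike, with a Spearman correlation of 0.817 (bootstrap 95% interval 0.809 to 0.825) and a Pearson correlation of 0.873 on log2 fold. These correlations run across peaks, which are not independent replicates. Summits lay a median of 25 bp apart, and 90% of the sites had summits within 75 bp. Median fold was 6.18 in replicate 1 and 5.37 in replicate 2, and 6562 sites, or 66.6%, had the higher value in replicate 1. Median width was 467 bp in replicate 1 and 378 bp in replicate 2. Each list was scaled to its own background, so a difference in fold between lists cannot by itself be read as a difference in occupancy.

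**Figure D2:**
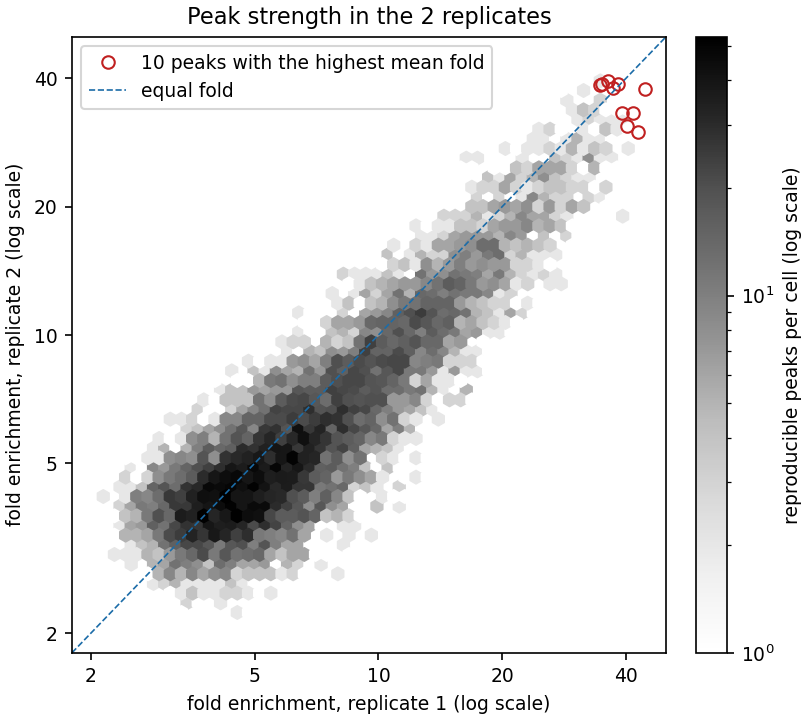
Fold enrichment of the 9858 shared sites in replicate 1 (horizontal, log scale) against replicate 2 (vertical, log scale); shading gives the number of sites per cell on a log scale, the dashed line marks equal fold and red circles mark the 10 sites of highest mean fold. Sites follow the line with a Spearman correlation of 0.817, and 66.6% lie on the side of replicate 1.

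The strongest shared sites spread over 6 chromosomes. They are named by position, in the coordinates of the peak lists, whose genome build is not given in the sources used here. The highest mean fold was at 21316522 to 21317476 on chromosome 8, with 41.1 ± 4.70 (SD, n = 2, as for the values that follow). On chromosome 9, the site at 5708884 to 5710377 reached 38.5 ± 0.36 and the site at 46609061 to 46609961 reached 36.2 ± 4.21. Chromosome 11 held sites at 34414110 to 34415118, with 37.7 ± 2.38, and at 2852589 to 2853607, with 37.5 ± 0.60. The site on chromosome 12, at 39597235 to 39598367, had 37.3 ± 5.94. On chromosome 3, enrichment was 36.8 ± 2.64 at 37825198 to 37826320 and 36.3 ± 8.995 at 23958389 to 23959865. On chromosome 17, enrichment was 36.6 ± 2.85 at 10222572 to 10224080 and 35.5 ± 6.47 at 12565060 to 12566132.

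With n = 2 and SDs from 0.36 to 8.995, the order among these 10 sites was not tested. Summits at each site were at most 22 bp apart between replicates, and fold was higher in replicate 1 at 5 of the 10. Of the 10, 4 were among the 10 highest shared sites of replicate 1 and 6 among those of replicate 2. Their recovered pileups, the number of ChIP fragments over the summit, were 349 to 449 in replicate 1 and 284 to 372 in replicate 2. The highest pileups anywhere in the lists were 468 and 434, each 2 times the recovered fragment length. If that value is a ceiling, a correction puts the pileups of the named sites 1.84 to 3.34 times too low in replicate 1 and 1.62 to 2.27 times in replicate 2. After it, 6 of the 10 stay among the strongest 10. The correction takes read starts as evenly spread and every discarded read as a separate fragment, not a PCR copy, and neither was tested. Both of the highest pileups stood at 1 region of chromosome 7, where replicate 1 had a single peak at 44130747 to 44133693 with 36.8-fold enrichment. There replicate 2 had 3 peaks, at 44130785 to 44131304, 44131416 to 44132154 and 44132385 to 44133672, with 9.90-fold, 15.0-fold and 33.5-fold enrichment. That region, singled out after its values were seen, is not counted as shared because no pair of peaks in it overlaps by 50% of both.

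**Figure D3:**
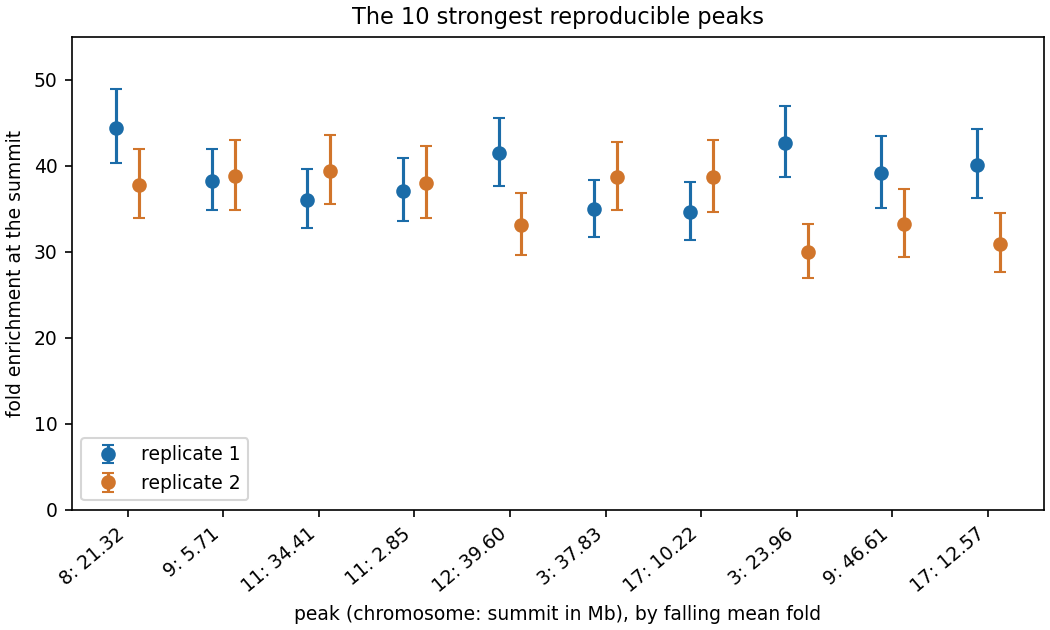
Fold enrichment at the summit (vertical axis) of the 10 shared sites of highest mean fold in replicate 1 (blue) and replicate 2 (orange), ordered by falling mean; bars are exact Poisson 95% intervals of the recovered pileup, which cover counting error only and allow for no ceiling on the pileup. All values lie between 30.0 and 44.4.

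Shared sites were concentrated toward the chromosome ends, a comparison added after the peak lists were seen. Over the 947 Mb up to the last peak of each of the 20 chromosomes there were 10.4 shared sites per Mb. Their density was 20.3 and 22.1 per Mb in the first and last 5% of the chromosomes and 2.53 per Mb just past the midpoint, at 50 to 55% of the length. The outer 25% at either end together held 7652 sites, or 78.0% (77.2 to 78.8%), where random placement on the same chromosomes gave 49.98 ± 0.54% and at most 51.4% (100 placements, one-sided permutation p = 0.0099). Such placement gives close to 50% by design and takes no account of where reads can be placed. The share of sites in these outer parts exceeded 50% on 19 chromosomes, from 69.7% on chromosome 8 to 92.1% on chromosome 4. Chromosome 13 was the exception, with 43.74% (40.1 to 47.4%). It had the highest density of all, 16.3 sites per Mb, yet the stretch from 10 to 20% of its length held 1 site. Chromosome 20 had the lowest density, 7.74 per Mb, and chromosome 2 the widest gap without a shared site, 6.59 Mb from 19.2 to 25.8 Mb.

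Sites of every strength lay mostly in the outer parts. Sites with a mean fold of at least 12 had 77.1% (74.8 to 79.3%) in the outer parts, and sites below 4-fold had 79.5% (77.5 to 81.5%). Median mean fold was 5.72 in the outer parts and 5.84 in the middle, a difference of −0.12 whose bootstrap 95% interval, −0.32 to 0.04, includes 0. Peaks found in replicate 1 alone had 79.0% (77.9 to 80.04%) in the outer parts and those found in replicate 2 alone 78.7% (75.1 to 82.0%). Positions relative to genes were not analysed here, because no gene annotation of the lists' build was used.

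**Figure D4:**
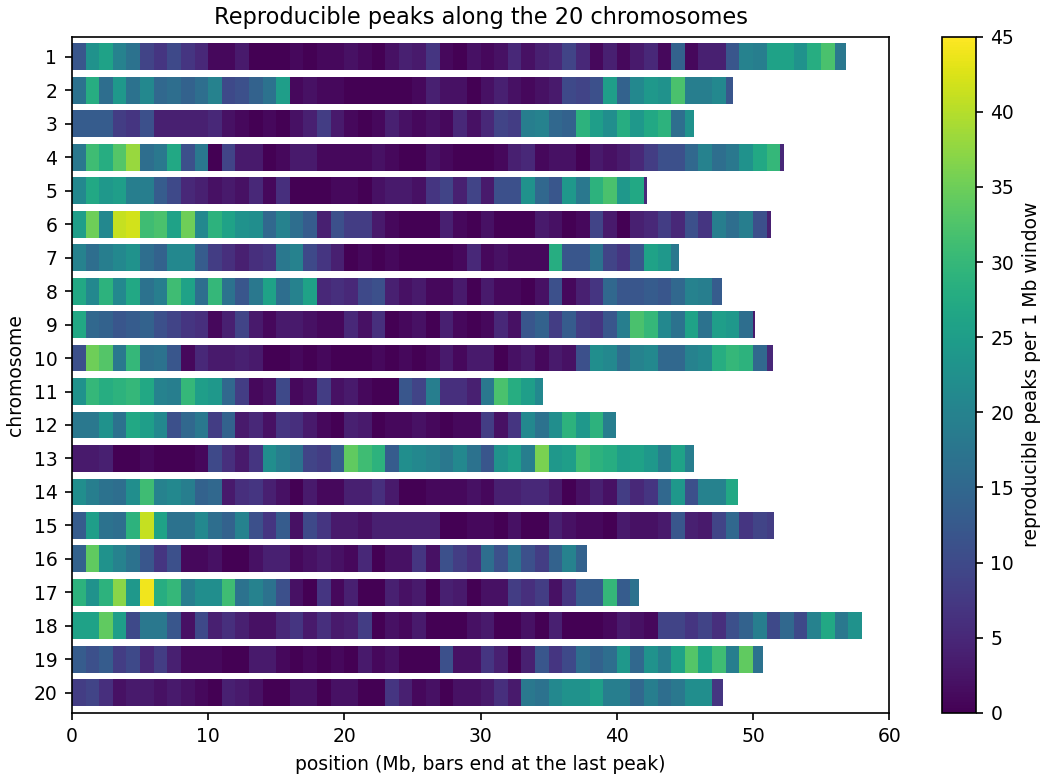
Shared sites per 1 Mb window (colour) along the 20 chromosomes, each bar ending at the chromosome's last peak (horizontal axis, Mb). The outer 25% at either end together hold over 50% of the sites on 19 chromosomes, while chromosome 13 is nearly empty at its start; the fullest window, on chromosome 17 from 5 to 6 Mb, holds 44 sites.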

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

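The alternatives for the share of replicate 2's peaks that were shared, for chromosome position, for spacing, for pileup and for the strongest sites were chosen after the results were seen; the others were planned. The number of shared sites stayed within 1.5 times of 9858 with −log10 q of at least 10 (7111), at least 4-fold enrichment (6964), overlap of at least 1 bp (10301), summits at most 100 bp apart (9768) and without scaffolds (9806), but was 4120 at an IDR of at most 0.01. Replicate 1 kept 9915 peaks at 4-fold, by construction of the threshold. The share of replicate 2's peaks that were shared, 90.03%, became 93.9% with the q threshold, 85.9% at 4-fold, 94.1% at 1 bp, 89.2% by summits and 37.6% by IDR, and the cause was not tested. The rank correlation was 0.888 with −log10 q in place of fold. Without chromosome 13, 80.8% of sites lay in the outer parts, and the lists of single replicates gave 78.3 to 78.5%. The excess of close pairs was 1.17-fold at 10000 bp. At 1000 bp the ratio was 0.818, which cannot be read as a deficit. Placed sites were free to overlap, whereas the closest shared summits were 376 bp apart. Single lists gave 1.44 to 1.55 at 3000 bp, and at 1000 bp 1.03 in replicate 1 and 1.19 in replicate 2. The log2 change of pileup at strong shared sites, −0.43, was −0.26 by deposited fold. Of the 10 named sites, single replicates kept 4 to 6, and a correction for 1 read per position and strand kept 6. No paired analysis was possible because only lists of the ChIP group were analysed here, 1 per replicate number. Position relative to genes, bound genes, gene lists among bound genes and motifs at summits, with their alternatives, were not run. Among the weakest 10% of replicate 1's peaks 23.2% had a counterpart. Recovered ChIP depth before scaling was nearly equal, 0.0336 reads per bp in replicate 1 and 0.0332 in replicate 2. That argues against a gap in ChIP depth before scaling as the cause. Replicate 2's pileups were scaled by 0.846 in its list, however, so its effective depth was lower. Whether that scaling, or the depth that both shared, set this low share was not tested.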

Other observations

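The tests in this part were chosen after the results were seen, except the test of weaker enrichment over all peaks.

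Close pairs of shared sites were more frequent than placement gave. Neighbouring summits at most 3000 bp apart formed 867 pairs, where moving sites within their own 100 kb gave 603 ± 20.9 (SD over 100 placements) and at most 657, so the excess was 1.44-fold. At distances of at most 1000 bp there were 168 pairs of shared sites against 205 ± 14.7 placed. In the single lists, replicate 1 had 547 against 532 ± 22.6 and replicate 2 had 308 against 260 ± 17.9. Placed sites were free to overlap, whereas the closest shared summits were 376 bp apart. The lower number of shared pairs at this distance therefore cannot be read as a deficit. At most 10000 bp apart there were 2153 pairs against 1838 ± 26.9. The median distance between neighbours was 35.2 kb. The densest windows of 50 kb held 7 sites, and 6 windows reached that number, on chromosomes 3, 8, 12, 13, 17 and 18. The window on chromosome 3, from 37800001 to 37850000, contains the named site at 37825198, and the 7 summits on chromosome 18 fell within 12.7 kb, with a highest mean fold of 33.6.

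A few peaks stood on a high background. In replicate 1, 33 peaks had a recovered background over 2 times the list's median, and in replicate 2 there were 51. On chromosome 13, between 38798721 and 38856052, replicate 1 had 5 such peaks with backgrounds of 33.4 to 38.2 against a median of 9.85, and enrichment from 1.88-fold to 3.60-fold. Replicate 2 had 2 such peaks there.

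Replicate 2 had fewer peaks at nearly the same recovered ChIP depth before scaling, 0.0332 against 0.0336 reads per bp. Before any scaling here, replicate 1 had 7809 peaks with −log10 p of at least 20, where replicate 2 has 5046. Scaling replicate 1 by 0.835, the ratio of the genome-wide backgrounds per bp of fragment, left 6709 of them. Scaling by 0.775, the ratio of the backgrounds themselves, left 6364. Scaling thus covers part of the difference in strong peaks but does not account for all of it. Replicate 1's pileups were then lowered by the change measured at shared sites with pileups of 90 to 220, −0.43 on the log2 scale. Of that change, −0.13 is expected from depth and fragment length and −0.30 lies beyond them. This left 4577 peaks, or 0.907 times replicate 2's number, within a 10% bound set after the results were seen. Because the change was measured between these same 2 lists, the near match describes how they differ and is no independent test of weaker enrichment. What lowered the pileups was not tested. Of the 2319 shared sites past −log10 p of 20 in replicate 1 alone, 1 had been used to measure the change. The change was smallest at pileups under 40, −0.19, and was −0.33 at 40 to 60, where both lists had to call the site. At 300 and above it was −0.30. An earlier test counted peaks past replicate 2's lowest −log10 p, 4.33, against the 10316 peaks of replicate 1 that overlap replicate 2. It kept 15794 after scaling, 1.53 times that number, and a mean of 13500 over 100 draws after lowering, 1.31 times. Both missed their bounds, and the bound for weaker enrichment had been set before that test was run. The count at −log10 p of at least 20 was added after that miss. The earlier test decides neither explanation, because these pileups had already been selected for passing replicate 1's threshold. The loss of weak peaks stays open, and no biological explanation was tested.

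Sites were sparse in chromosome middles. Low coverage that hides only weak peaks cannot account for the spread of strong ones, and 77.1% (74.8 to 79.3%) of sites of at least 12-fold lay in the outer parts. Since the true spread of sites is not known, that share does not show whether weak peaks were also hidden in the middle. Stretches where reads cannot be placed remain open: in replicate 1, 7.97% (7.08 to 8.94%) of middle peaks stood on the genome-wide background against 2.69% (2.41 to 2.99%) of outer ones, while the median background at middle and outer peaks was nearly equal, 9.78 and 9.85, and the input over the whole middle was not analysed here. Gene density, known to be higher toward the ends of soybean chromosomes, could also underlie the distribution and was not tested, since no annotation of the lists' build was used.

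The strongest peaks may be compressed. The highest pileup, 468 in replicate 1 and 434 in replicate 2, was exactly 2 times the fragment length recovered from the background steps, 234 and 217 bp, which is the most that 1 read kept per position and strand allows. At the 122 shared sites with a geometric mean pileup of at least 300, the log2 ratio between replicates had a robust SD of 0.073 (0.056 to 0.089) against 0.111 from counting noise and 0.056 with such a ceiling. The 95% interval of the robust SD also lay below counting noise for pileups of 220 to 260 and for those under 60, far from a ceiling, but included it in each narrow range between 60 and 220 (not when 90 to 220 were pooled, 0.171 against 0.184) and from 260 to 300, so the scatter alone does not single out a ceiling. If a ceiling holds, the order of the 10 named sites would be uncertain. Their pileups would be understated 1.84 to 3.34 times in replicate 1 and 1.62 to 2.27 times in replicate 2. Those factors also assume evenly spread read starts and no PCR copies among the discarded reads. No biological explanation was tested.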
